A study of Mus musculus with 2 samples.

How the data were processed

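The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of H3K27ac, the acetylated form of histone H3 found at active promoters and enhancers, in mouse liver at embryonic day 12.5. Per the labels, the tissue came from B6NCrl embryos of both sexes, 120 embryos in replicate 1 and 88 in replicate 2, so each of the 2 biological replicates is a pool of many embryos and the spread between embryos cannot be seen. Both libraries belong to 1 group, and no second tissue, stage or treatment was compared. Replicate numbers were taken from the labels.

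The authors deposited 4 peak lists on the mm10 assembly: 1 per replicate, 1 pooled list called on both replicates' alignments together, and 1 list of replicated peaks. Per the deposited file descriptions, the per-replicate and pooled lists were derived from the replicates' alignments and from further files whose content is not described, and the replicated list was derived from the pooled and the per-replicate lists. The rule for calling a peak replicated, the aligner, the peak caller and their versions are not given in the sources used here. Every row of the replicated list was an exact copy of a row of the pooled list, when tested on the files. For each peak the authors deposited a fold enrichment, which is a linear ratio, with −log10 p and −log10 q values. All deposited −log10 p values were above 2, and the smallest deposited −log10 q was 0.325, so the per-replicate and pooled lists include weak peaks. The labels name a possible control experiment, and which control library entered each list is not stated. The authors also deposited the offset of each peak's summit from its start. Fold enrichments are the authors' values for each peak and served here to describe, rank or filter peaks within a list, for a correlation between the replicates, and, after the data were examined, for a comparison of each list's median promoter fold enrichment with random lists.

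The lists hold no read counts. The depth of each library is therefore unknown, and no interval for a fold enrichment can be given. Intervals printed beside shares are 95% Wilson intervals and cover counting error over peaks only. Peaks and genes are not independent replicates, and neighbouring genes share peaks, so every p-value describes these libraries and not the variation between embryos. The list tests counted the members of a list as separate genes. Globin and Hox genes lie in clusters, so the p-values of these lists overstate the evidence. Other lists can hold neighbouring genes as well, and linkage was not accounted for in any list.

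Genes and transcription start sites (TSS) came from GENCODE release M21 for the same assembly, and sequence from the reference assembly whose chromosome lengths equal those of mm10. All protein-coding TSS of 21853 protein-coding genes on the assembled chromosomes were used. Overlap of 1 bp counted as shared. A promoter was the TSS with 1 kb on either side, and any other peak was called distal. A gene's promoter fold enrichment was the highest fold enrichment among the peaks that reached into its promoters. It is the value of the whole peak, which can extend far beyond the promoter. The replicated list was the main list. Shares of overlap were set beside those after 100 circular shifts of a list along each chromosome.

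Before the data were examined, 25 gene lists for cell types and functions were fixed: globin, erythroid, stem and progenitor, megakaryocyte, macrophage, granulocyte, B lymphoid, T lymphoid, hepatic secreted protein, hepatic transcription factor, hepatoblast and bile duct epithelium, postnatal hepatocyte metabolism, iron handling, endothelial, stellate and mesothelial, cell cycle, ribosomal protein, imprinted and fetal growth, Hox, and 6 lists of other tissues (neuronal, skeletal and cardiac muscle, pancreas, gut and lung epithelium, skin, germ cell). Of 575 symbols, 574 matched the annotation. Ahsp, an erythroid gene, did not match and was not analysed here, and 2 symbols of the same imprinted gene were counted once. Each list's share of members with a promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test. The median length of replicated peak within 50 kb of the gene's TSS was ranked among 10000 random lists of the same size, matched in deciles on the number of TSS in that window. These p-values are two-sided and called permutation p, and 0.0002 is the smallest that 10000 lists can give. Peaks at most 12.5 kb apart were stitched into domains, which were ranked by the sum over peaks of width times fold enrichment. Domains beyond the point where the scaled ranked curve has slope 1 were called large, and a domain was assigned to the genes with a TSS inside it or, failing that, to the nearest gene. List membership of large domains was compared by a two-sided Fisher's exact test. For the replicates, genes with a promoter peak in only 1 replicate's own list were compared by exact binomial (McNemar) tests, per list against the ratio over the other genes.

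Distal replicated peaks were searched for 13 known binding sequences, or controls, within 250 bp of the summit on either strand. Each window was paired with the window 5 kb downstream, where this lay outside the peaks of all 4 lists, and the pairs were compared by exact two-sided McNemar tests. Of 34877 distal peaks, 21179 had such a control window. Benjamini-Hochberg adjustment was applied over the 25 lists or the 13 sequences of each test, with 0.05 as threshold.

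The rule for named genes was also fixed beforehand: per list the 4 members with most replicated peak length within 50 kb, up to 4 members without a promoter peak in liver and blood lists (alphabetically) or with 1 in lists of other tissues (by fold), the genes of the 20 domains of highest rank, the 5 widest and 5 highest-fold peaks, and 25 genes fixed whatever their values. Alternatives fixed beforehand were each replicate's own list in place of the replicated list, the pooled list, peaks with −log10 q of at least 5, 50% reciprocal overlap, the 20000 strongest peaks per replicate, other promoter windows (500 bp and 2.5 kb), 1 TSS per gene, random lists matched on promoter CpG content (observed over expected, within 500 bp of the TSS), windows of 20 and 100 kb, unmatched random lists, leaving out promoter peaks, stitching at 5 kb, reversed binding sequences, and 100 bp around the summit. After the data were examined, 1 more was added: only replicated peaks that overlap a peak in both replicates' own lists.

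The routines were tested on simulated data. All 2000 simulated intervals received the right overlap call and covered length. In lists simulated at 90% against 50%, the Fisher test called 93.8% of 1300 raised lists and 1.5% of 1000 others. The random-list test called 98.1% of 260 lists raised 3-fold and 3% of 200 others. A sequence planted in 10% of 3000 windows was found in 10.3% of them and in 0.0667% of control windows. Replicated peaks on sequences outside the assembled chromosomes were left out of the gene and motif analyses; there were 6. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.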

Results

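H3K27ac was mapped by ChIP-seq in the mouse liver at embryonic day 12.5, when the organ is the main site of blood formation and also holds hepatoblasts, endothelium and mesenchyme. There were 2 biological replicates of 1 group, each from a pool of embryos (120 in replicate 1, 88 in replicate 2). Replicate 1 had 77881 peaks in its own list, covering 44.9 Mb. Replicate 2 had 90689 peaks covering 55.9 Mb. The pooled list had 106360 peaks, and the replicated list 49470 peaks that covered 55.3 Mb, with a median width of 668 bp and a median fold enrichment of 4.04. Read depth was unknown.

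The peaks of highest fold enrichment and greatest width were taken from the replicated list. That list was derived from the pooled and per-replicate lists, so finding its strongest peaks in both replicates is no separate evidence of recurrence. The peak with the highest fold enrichment in the replicated list, 70.9, lay at the start of Tcta (chromosome 9, 108304832 to 108307339, mm10), and the overlapping peaks had a fold enrichment of 58.5 in replicate 1 and 64.7 in replicate 2. The next ranks were held by peaks at the histone genes Hist1h2be (65.4) and Hist4h4 (65.0), at Samd14 (62.9) and at Setd5 (62.8). The widest peak spanned 52.3 kb of Zfpm1, which encodes the GATA1 cofactor FOG1 (chromosome 8, 122280106 to 122332441), and its midpoint was intronic. It was followed by peaks of 36.3 kb at Ank1, the gene of the red-cell membrane protein ankyrin, 21.4 kb at Rbm38, one of nearly the same width 38.5 kb from Pim1, and 19.9 kb at Hemgn, an erythroid nuclear protein gene.

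Between the replicates, 70.3% of replicate 1's peaks (95% interval 70.0 to 70.6) overlapped a peak of replicate 2, and 53.1% of replicate 2's peaks (52.7 to 53.4) overlapped a peak of replicate 1. Circularly shifted lists gave a mean of 3.83% and at most 4.69%. Sharing depended on strength. All peaks in the top decile of −log10 p were shared in either replicate, against 37.7% of the weakest decile in replicate 1 and 23.0% in replicate 2. With 50% reciprocal overlap the shares were 38.2% and 32.8%. Across the 40680 replicated peaks that overlapped a peak in both own lists, the replicates' fold enrichments had a Spearman correlation of 0.786 and a Pearson correlation of 0.894 on the log2 scale. These correlations are across peaks of 2 libraries, and peaks are not independent replicates. The other 8784 replicated peaks (17.8%) did not overlap a peak in both own lists. Their median fold enrichment was 3.07, against 4.56 for those that did.

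**Figure D1:**
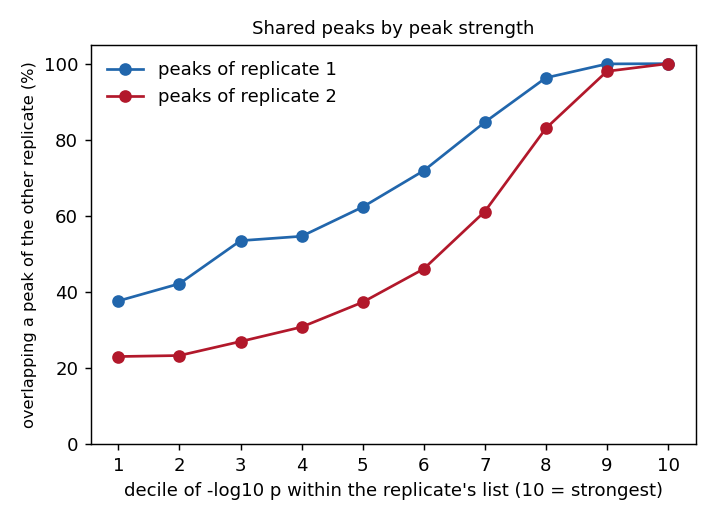
Percent of each replicate's peaks that overlap a peak of the other replicate by at least 1 bp (vertical axis), by decile of −log10 p within the replicate's own list (horizontal axis, 10 is the strongest). The shares run from 37.7% (replicate 1, blue) and 23.0% (replicate 2, red) in the weakest decile to 100% in the strongest.

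Promoter peaks were stronger and wider, and distal peaks were more numerous. A peak counted as a promoter peak if any part of it lay within 1 kb of a TSS. Wide peaks were therefore more likely to count, and the difference in width is partly set by this definition. Of 49464 replicated peaks on the assembled chromosomes, 14587 lay within 1 kb of a protein-coding TSS, or 29.5% (29.1 to 29.9), against a mean of 3.90% for shifted peaks. Promoter peaks had a median width of 1067 bp and a median fold enrichment of 7.61. The 34877 distal peaks had medians of 581 bp and 3.67, and their midpoints were 60.7% intronic, 34.1% intergenic and 5.22% exonic. Peaks that overlapped the replicated list were stronger and more often promoter peaks. Of replicate 1's peaks, 29.7% of those that overlapped it (median fold enrichment 3.73) and 7.84% of the others (2.86) lay at promoters, an odds ratio of 4.96. In replicate 2 the shares were 28.3% (median 4.22) and 9.04% (3.02), an odds ratio of 3.97. Strength and width were not matched in this comparison. Both two-sided Fisher's exact tests gave p-values too small for double precision to hold. The promoter share moved with the list and window, from 18.6% in the pooled list to 37.5% with 2.5 kb around the TSS.

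Most genes of the erythroid, globin, cell cycle and ribosomal protein lists and of 2 hepatic lists carried acetylated promoters, and genes of other tissues largely did not. Of 21853 protein-coding genes, 10990 (50.3%) had a replicated promoter peak. All 7 globin genes had 1 (adjusted p = 0.0230), and so had 40 of 42 erythroid genes (95.2%, adjusted p = 5.09e-09, Fisher's exact test with Benjamini-Hochberg adjustment, as for the other lists). Among the globin genes, the adult genes Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), Hbb-bt and Hba-a1 had promoter fold enrichments of 29.9, 23.8 and 32.2. The embryonic genes Hba-x, Hbb-y and Hbb-bh1 had 31.9, 12.6 and 10.5. The Hba-a1 start (chromosome 11, 32283511) lay between replicated peaks that ended at 32283472 and began at 32284381. The first peak gave the value of Hba-x, and the second that of both Hba-a1 and Hba-a2. These alpha-globin values therefore do not compare separate promoters. The erythroid transcription factor genes Klf1 (ENSMUSG00000054191, chromosome 8, 84901928 to 84905291), Tal1 (ENSMUSG00000028717, chromosome 4, 115056426 to 115071755) and Gata1 (ENSMUSG00000031162, chromosome X, 7959260 to 7978071) had promoter fold enrichments of 42.5, 36.4 and 20.1 in the replicated list. In the own lists of replicates 1 and 2, Klf1 had 32.1 and 37.9, Tal1 23.6 and 42.8, and Gata1 17.5 and 19.4. Epor, the erythropoietin receptor gene, had 27.1. The 2 erythroid members without a promoter peak were Car1, a carbonic anhydrase gene, and Slc25a37, which encodes a mitochondrial iron importer. All 27 cell cycle genes (adjusted exact p = 1.24e-07) and all 37 ribosomal protein genes (adjusted p = 3.61e-10) had a promoter peak. Promoter values of 32.9 at Cdc6 and 21.8 at Rpl3 were among them. The cytoskeletal gene Actb, which belonged to no list, had 52.2.

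Hepatic lists differed among themselves. In the hepatic secreted protein list, 26 of 33 members had a promoter peak (78.8%, adjusted exact p = 0.00253), with 4.91 at Alb, the albumin gene (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), 3.18 at Afp (alpha-fetoprotein), 3.78 at Apoa1, 13.5 at Apoe and 18.1 at Apoa2. Apoc1 of the same list had the same value as Apoe, so a shared peak may count for both. The hepatic transcription factor list had 18 of 22 (81.8%, adjusted exact p = 0.00723), with 7.08 at Cebpa and 4.73 at Foxa2. Hnf4a, the gene of a main hepatocyte regulator (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910), had no replicated promoter peak, although each replicate's own list held a weak peak (3.10 and 3.52). The call of the secreted protein list ended with peaks of −log10 q of at least 5 (66.7%, adjusted exact p = 0.0746). The postnatal hepatocyte metabolism list was lower than other genes, at 8 of 34 (23.5%, adjusted exact p = 0.00315). Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis, and the urea cycle genes Arg1 and Cps1 had no promoter peak, and Asl had a peak of 19.7. This difference ended against random lists matched on promoter CpG content, whose median was 20.6% (adjusted permutation p = 0.871). Hepatoblast and bile duct genes had 7 of 15 (46.7%, adjusted exact p = 0.832), among them Dlk1 at 8.50, and Epcam and Cdh1 had none. Iron handling genes had 9 of 15 (60.0%, adjusted exact p = 0.690), with the ferritin genes Fth1 at 42.9 and Ftl1 at 35.9, while Hamp, the hepcidin gene, had none.

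Markers of other blood and stromal cells differed from list to list. Stem and progenitor genes had a promoter peak in 16 of 24 (66.7%, adjusted exact p = 0.199), with 22.8 at Runx1 and none at Gata2, Cd34 or Flt3. In replicate 1's own list they had 18 of 24 and passed (adjusted exact p = 0.0348). Megakaryocyte genes had 15 of 21 (71.4%, adjusted exact p = 0.109), with 24.6 at Gp9, and passed the threshold against CpG-matched random lists (adjusted permutation p = 0.000714) and with either replicate's own list (81.0% in replicate 1, 85.7% in replicate 2). Macrophage genes had 9 of 24 (37.5%, adjusted exact p = 0.270), with 5.40 at Spi1, which encodes PU.1, and none at Adgre1 or C1qa. Granulocyte genes had 3 of 16 (18.8%, adjusted exact p = 0.0191), with 4.25 at Mpo. That difference ended with either replicate's own list (4 of 16, adjusted exact p = 0.0582 and 0.0577) and against CpG-matched lists (adjusted permutation p = 0.95). B lymphoid genes had 0 of 16 (adjusted exact p = 6.91e-05) and T lymphoid genes 1 of 17 (5.88%, adjusted p = 0.000303), namely Lck at 11.9. The T lymphoid difference did not pass against CpG-matched lists (adjusted permutation p = 0.0573). Endothelial genes had 12 of 26 (46.2%, adjusted exact p = 0.760), with 3.31 at Cdh5, the VE-cadherin gene, and 7.11 at Egfl7. In the pooled list they had 80.8%, above other genes (adjusted exact p = 0.0138). Stellate and mesothelial genes had 12 of 22 (54.5%, adjusted exact p = 0.832), with 11.8 at Reln, and imprinted and fetal growth genes 11 of 16 (68.8%, adjusted p = 0.263), with 30.4 at Igf2bp3.

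**Figure D2:**
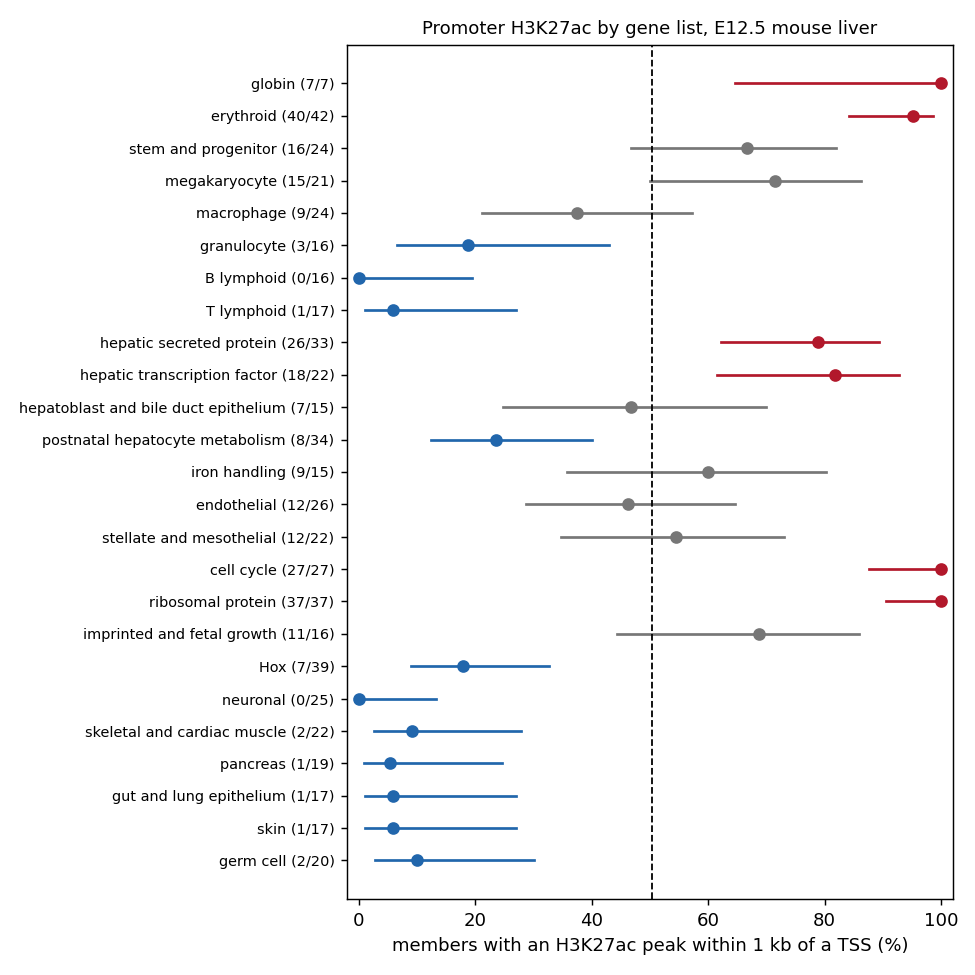
Percent of each list's members with a replicated H3K27ac peak within 1 kb of a TSS (points, with 95% Wilson intervals as bars and the members with a peak over all members in brackets). The dashed line is the 50.3% of all protein-coding genes; red lists lie above and blue lists below other genes at an adjusted p under 0.05, and grey lists pass in neither direction. The erythroid list stands at 95.2%, and the neuronal list at 0 of 25.

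Promoters of other tissues were mostly unmarked. No neuronal gene of 25 had a promoter peak (adjusted exact p = 1.59e-07). Neurod1 of neurons, Myod1 of muscle and Hoxa9 were among the unmarked genes. The counts were 2 of 22 for skeletal and cardiac muscle (9.09%, adjusted exact p = 0.000188), 1 of 19 for pancreas (5.26%, adjusted p = 0.000136), 1 of 17 for gut and lung epithelium (5.88%, adjusted p = 0.000303), 1 of 17 for skin (5.88%, adjusted p = 0.000303) and 2 of 20 for germ cells (adjusted p = 0.000425). The skin difference did not pass against CpG-matched lists (adjusted permutation p = 0.375). The marked members were Mylpf at 35.1 and Tnni1 at 2.82 among muscle genes, Cela1 at 4.64, Lgr5 at 3.47, Krt10 at 10.4, Zpbp at 11.6 and Dazl at 4.37. The Mylpf peak also held the TSS of Tbc1d10b, so it cannot be given to either gene. Hox genes had 7 of 39 (17.9%, adjusted exact p = 0.000136), all of them from Hoxa1 to Hoxa4 and from Hoxb2 to Hoxb4, with 9.39 at Hoxb2 and 7.98 at Hoxb4.

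Acetylation extended far around erythroid genes. The median length of replicated peak within 50 kb of the TSS was 24005 bp for the erythroid list, against 2853 bp for matched random lists, and 51705 bp against 10108 bp for the globin list (both permutation p = 0.0002, adjusted p = 0.00167). Clustered globin and Hox genes share windows, while random lists drew unlinked genes, so the p-values of the globin and Hox lists overstate the evidence. Hbb-bs had 50.1 kb of peak in this window, Hemgn and Zfpm1 lay above the 99th percentile of all genes, and Tal1 had 41.9 kb. Against these, Alb had 6.29 kb, Afp 5.44 kb and Cdh5 1.53 kb. Medians were also higher than in random lists for ribosomal protein genes (13811 bp, adjusted permutation p = 0.00250), cell cycle genes (9365 bp, adjusted p = 0.0229), imprinted and fetal growth genes (7042 bp, adjusted p = 0.0160) and hepatic transcription factors (5915 bp, adjusted p = 0.0225). The Hox list was lower (302 bp against 10367 bp, adjusted permutation p = 0.00167). The other 18 lists did not pass, among them hepatic secreted protein at 5442 bp (adjusted permutation p = 0.504). Stem and progenitor genes passed in the pooled list (adjusted permutation p = 0.0256), as did skin genes on the low side (0.0433), which also passed with the 100 kb window (0.0300). Without promoter peaks the erythroid median was 10124 bp against 566 bp (adjusted permutation p = 0.00250). The calls of the hepatic transcription factor, imprinted and Hox lists ended with unmatched random lists (adjusted permutation p = 0.189, 0.182 and 0.0520) and with a 100 kb window (0.0806, 0.0800 and 0.145). Without replicate 2 the imprinted list also fell short (adjusted permutation p = 0.111). The cell cycle call ended with −log10 q of at least 5 (adjusted permutation p = 0.0557) and without promoter peaks (0.0622).

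The domain of highest rank held the alpha-globin genes, and of the 20 domains of highest rank, ranks 6, 7, 9 and 18 held genes of the erythroid list and ranks 2 and 14 histone genes. The others held none of these. Only protein-coding genes were assigned to domains. The microRNA genes Mir144 and Mir451a lay inside the domain of rank 16, and the non-coding gene Mir142hg inside that of rank 11. Stitching gave 14854 domains, of which 1002 were large and held 54.3% of the summed width times fold enrichment. The alpha-globin domain covered 112 kb (chromosome 11, 32195299 to 32307664), with 77.9 kb of peak from Il9r through Nprl3 to Hba-a2. In the own lists, replicate 1 had 70.8 kb and replicate 2 75.4 kb of peak there. The histone genes of ranks 2 and 14 belong to the Hist1 cluster on chromosome 13. Ranks 3 and 4 were gene-dense stretches of chromosome 10. Pim1, Zfpm1, Hemgn, Hipk2 and Ank1 lay in or next to ranks 5 to 9, followed by Col5a1 with Fcnb, Tspoap1 and Bmp2k in ranks 10 to 12. Lmo2, which encodes a partner of TAL1, was at rank 18, and Kcnn4 at rank 20. Large domains were assigned to 35 of 42 erythroid genes (83.3%, against 9.91% of other genes, adjusted p = 3.13e-27, Fisher's exact test) and to all 7 globin genes (adjusted p = 1.29e-06). The alpha-globin genes of the list shared the domain of rank 1, so the globin test counts linked genes as separate and overstates the evidence. No other list passed. Hepatic secreted proteins had 4 of 33 (12.1%, adjusted exact p = 0.889), and cell cycle genes 7 of 27 (25.9%, adjusted p = 0.0751). No list lay below other genes; at an unadjusted p under 0.05 there were 2, Hox (0 of 39, exact p = 0.0295) and postnatal hepatocyte metabolism (0 of 34, p = 0.0445). With 1 replicate's own list, cell cycle genes (40.7% without replicate 2, 37.0% without replicate 1) and ribosomal protein genes (35.1% and 43.2%) also passed, and Hox genes lay below other genes (0 of 39 in either). Postnatal hepatocyte genes lay below without replicate 1 (0 of 34, adjusted exact p = 0.0457) and not without replicate 2 (3 of 34). In the pooled list ribosomal protein genes passed (adjusted exact p = 0.00956), and Hox genes lay below (adjusted p = 0.0285). Of the 20 domains named, 7 stayed among the first 20 without promoter peaks, and 13 with 5 kb stitching. The globin and histone genes have near-identical copies, so the placing of reads there is uncertain.

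**Figure D3:**
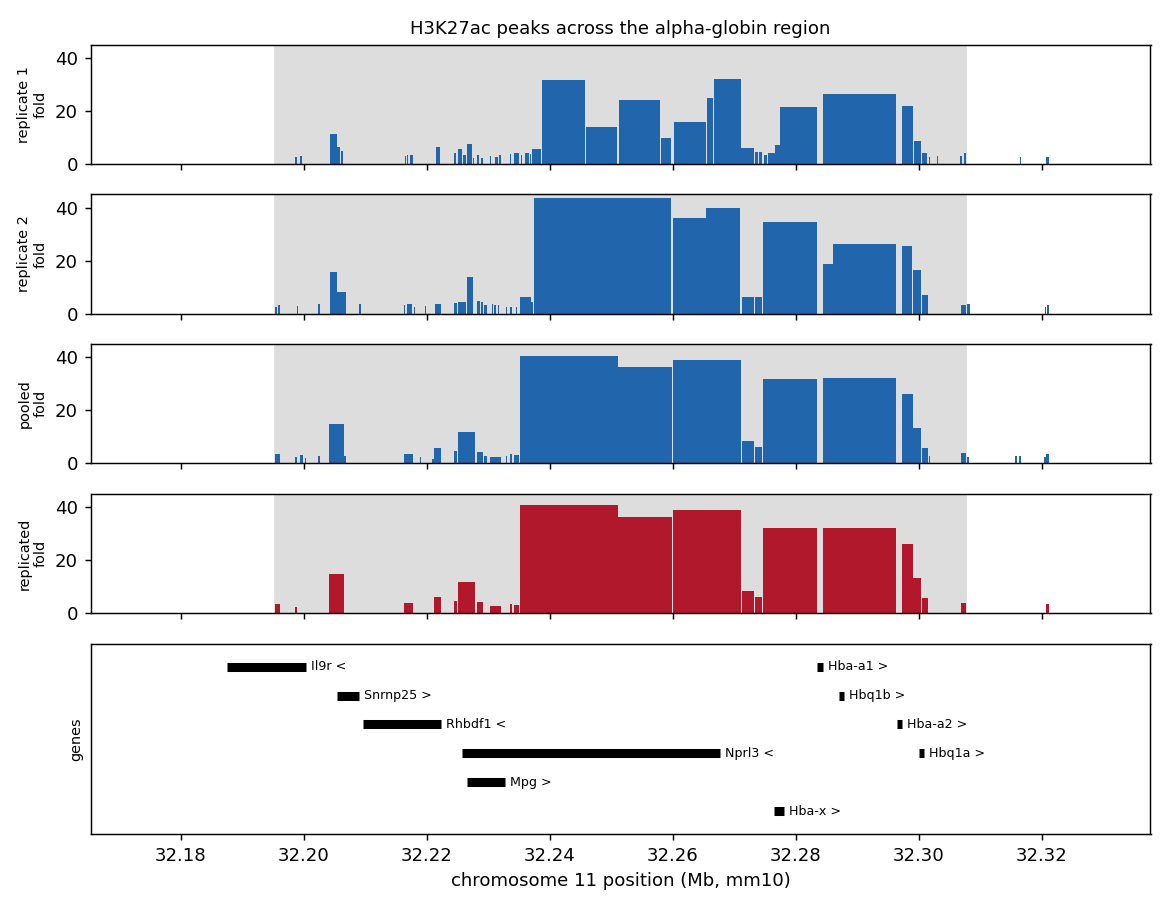
Map of the alpha-globin region of chromosome 11 (horizontal axis, Mb in mm10) with the peaks of the 4 deposited lists, each drawn at its width and with its fold enrichment as height, and the annotated protein-coding genes below (> plus strand, < minus strand). Grey marks the domain of rank 1, which holds 77.9 kb of replicated peak.

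Within 250 bp of the summit, distal peaks carried several binding sequences more often than their control windows, of blood factors and also of hepatocyte factors. The sequence of NFE2 and MAF-AP1 dimers (TGCTGASTCA) was found in 1.39% of peak windows and 0.477% of control windows, a ratio of 2.92 (adjusted p = 4.11e-23, exact McNemar test over 21179 pairs, as below). The PU.1 ETS sequence had a ratio of 1.62 (adjusted exact p = 8.86e-22). The composite of GATA with an upstream E-box element, bound by GATA1 and TAL1 complexes, had 1.36 (13.2% against 9.70%, adjusted exact p = 2.07e-29), and the GC box of KLF and SP factors 1.27 (adjusted p = 8.83e-87). Of hepatocyte sequences, HNF4 had a ratio of 1.30 (adjusted exact p = 0.0137) and FOXA 1.21 (adjusted p = 1.88e-07), while HNF1 at 1.63 (adjusted p = 0.415) and CEBP at 1.52 (adjusted p = 0.192) did not pass. RUNX had 1.11 (adjusted exact p = 0.0131). The simple GATA sequence WGATAR had 1.03 (61.0% against 59.5%, adjusted exact p = 0.00214), and its reversed form, a control for base composition, 0.871 (adjusted p = 4.68e-46). The controls MEF2 (1.10, adjusted exact p = 0.406) and RFX (1.31, adjusted p = 0.511) did not pass. The RFX ratio exceeded those of HNF4, the GC box, FOXA and RUNX. RFX was found in only 0.0992% of peak windows and 0.0755% of control windows, so it was too rare to set these ratios apart from a control. Within 100 bp of the summit several of these calls ended: NFE2 and MAF-AP1 had 1.59 (adjusted exact p = 0.0730), the GATA and E-box composite 1.06 (adjusted p = 0.327) and HNF4 1.45 (adjusted p = 0.0770). In that window the sequences more frequent than in control windows at an adjusted p under 0.05 were the GC box (1.31) and PU.1 (1.32), WGATAR was less frequent (0.805), and FOXA (0.917) and RUNX (0.921) did not pass. WGATAR also turned to 0.992 in replicate 1's own list and 0.993 in the pooled list without passing, and FOXA to 0.821 against its reversed form in the same windows. In replicate 2's own list the WGATAR call ended as well (1.01, adjusted exact p = 0.188). CEBP passed in replicate 1's list (2.00), replicate 2's list (2.03), the pooled list (1.88) and with peaks in both own lists (2.23), and HNF1 in replicate 2's list (2.36). The control RFX passed in the pooled list (1.55), and against their reversed forms both controls passed, with 3.50 for RFX and 2.21 for MEF2. These ratios exceeded those of the GATA and E-box composite (1.88), HNF4 (1.86), RUNX (1.64), WGATAR (1.31), PU.1 (1.23) and the GC box (1.08) in that comparison, which therefore does not set these sequences apart from the controls. NFE2 and MAF-AP1 lay above both controls, at 26.8. The reversed form of this sequence contains CpG, which the sequence itself lacks, and was found in only 0.0519% of peak windows. This ratio therefore depends on the control form and does not set the sequence apart either. HNF1 (3.25, adjusted exact p = 0.0531) and CEBP (1.17, adjusted p = 0.620) did not pass against their reversed forms. Peak windows were richer in G and C (48.3%) than control windows (44.9%).

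**Figure D4:**
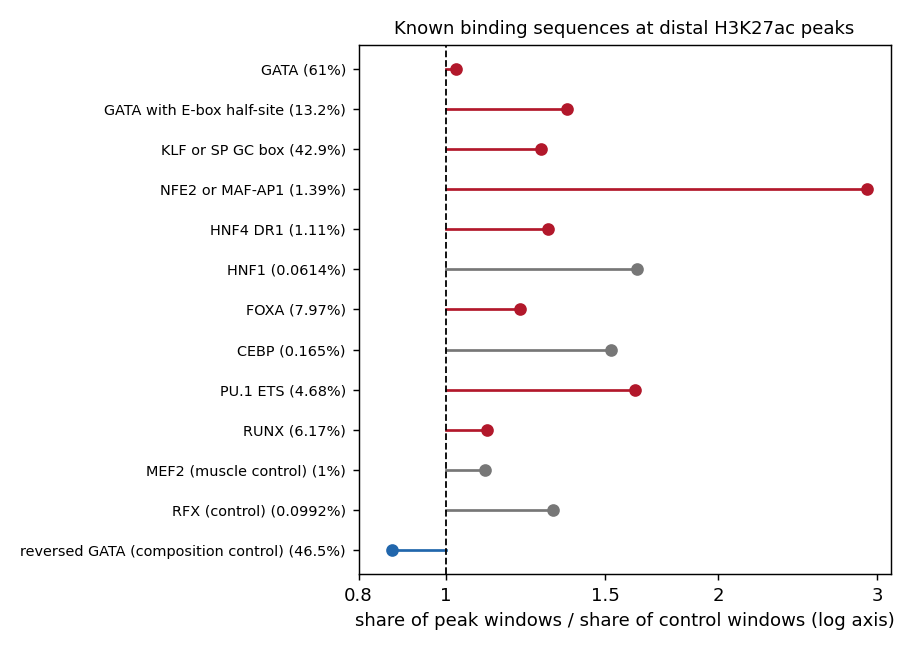
Share of distal peak windows holding each sequence, divided by its share of paired control windows (log axis), with the percent of peak windows in brackets. Red sequences were more frequent and blue less frequent in peak windows at an adjusted p under 0.05; grey ones passed in neither direction. The NFE2 and MAF-AP1 sequence lies farthest to the right at 2.92.

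The replicates differed in how many promoters were marked. Promoter peaks were found in both own lists at 10820 genes, in replicate 1 alone at 394 and in replicate 2 alone at 766, so replicate 2 had more (p = 4.34e-28, exact two-sided binomial test, which compares these 2 libraries). With the 20000 strongest peaks of each replicate, 259 and 668 genes were discordant, 72.1% of them with their peak in replicate 2. In the full own lists, no discordant gene was found among globin, erythroid, cell cycle or ribosomal protein genes. The same held for the hepatic transcription factor, granulocyte, neuronal, pancreas, gut and lung, and skin lists. The lists held 0 to 6 discordant members each, too few for nearly any of them to pass an adjusted threshold alone, so whether single lists differed between the replicates is open. By the exact binomial test 0 of 25 passed, and 1 did at an unadjusted p under 0.05, the T lymphoid list (3 members in replicate 1 alone and 0 in replicate 2 alone, p = 0.0386, adjusted p = 0.965).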

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

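With 2 replicates of 1 group there was no test for a sample far from the others or for a difference between groups. What follows concerns signal in data outside the gene comparisons.

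The annotation's long intergenic non-coding RNA genes entered no comparison. Of 5197 such genes over 5 kb from any protein-coding TSS, 421 had a replicated peak within 1 kb of the 5′ end, or 8.10% (95% Wilson interval 7.39 to 8.87), and at 377 of these a peak was present in both replicates' own lists. At the same distance the share was 11.9% (10.4 to 13.5) for antisense RNA genes, 5.69% (4.68 to 6.90) for microRNA genes, 4.69% (3.63 to 6.04) for small nuclear RNA genes and 1.69% (1.45 to 1.98) for processed pseudogenes. Shifted lists were not run for these genes, so how far the shares differ from random placement of peaks was not tested. Malat1, a nuclear RNA made in most cells, had a fold enrichment of 39.2. Among the 10 of highest fold enrichment were also Lockd (45.8) and Bloodlinc (37.8), both known from red-cell precursors; these names were chosen after their values were seen.

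The replicated list held 6 peaks on sequences outside the assembled chromosomes, which were left out of every gene comparison. The strongest, 1980 bp wide, had a fold enrichment of 49.5 and lay on a sequence assigned to chromosome 4 but not localised on it. The other peaks had values from 1.61 to 6.93.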

How the results depend on the processing

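All alternatives were planned except the restriction to peaks in both replicates' own lists, chosen after seeing the data. Of 716 values of single lists and sequences under alternatives, 622 kept their direction and their side of the threshold, 25 gained a call, 19 lost theirs and 50 changed direction. In 9 of these 50 either value had passed the threshold; the others passed on neither side. The erythroid list passed at promoters, within 50 kb and in large domains under every alternative run. Except where a list's length or a window's width sets the value, the cause was not tested.

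Replicate overlap, 70.3% and 53.1% for replicates 1 and 2, was 38.2% and 32.8% with 50% reciprocal overlap, 91.0% and 62.2% with −log10 q of at least 5, and 89.7% and 80.5% with the 20000 strongest peaks. The correlation of 0.786 was 0.863 with 50% reciprocal overlap. The promoter share of 29.5% ranged from 21.5% to 24.3% with 1 replicate left out. It was 18.6% in the pooled list, 34.3% with −log10 q of at least 5, 33.0% with peaks in both own lists, 26.8% at 500 bp, 37.5% at 2.5 kb and 24.7% with 1 TSS per gene.

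Lists below other genes at promoters numbered 11, and 7 against CpG-matched lists, where the granulocyte (18.8%) and postnatal hepatocyte (23.5%) lists moved to just above the matched median. The endothelial list moved above other genes in the pooled list (80.8%). Within 50 kb, lists below random lists numbered 1, with 2 in the pooled list and 0 against unmatched lists. Lists above other genes in large domains numbered 2, and 4 with either replicate left out. Lists below numbered 0, with 1 to 2 when 1 replicate was left out and 1 in the pooled list.

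Sequences above control windows numbered 8, and 2 within 100 bp of the summit; those below numbered 1, with 2 within 100 bp and 2 against reversed sequences. WGATAR turned from 1.03 to 0.992 in replicate 1's own list (1.01 in replicate 2's), 0.993 in the pooled list and 0.805 within 100 bp. FOXA turned to 0.821 against its reversed form and 0.917 within 100 bp, and RUNX to 0.921 within 100 bp.

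Changes of direction without a call were as follows. At promoters, the hepatoblast and bile duct list moved above other genes without replicate 1 (53.3%, against 46.7% without replicate 2) and in the pooled list (60.0%), the endothelial list without replicate 1 (61.5%) and the macrophage list in the pooled list (62.5%). Stellate and mesothelial genes moved below with 1 TSS per gene (45.5%). Against CpG-matched lists the macrophage (37.5%) and endothelial (46.2%) lists moved above.

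Within 50 kb, medians moved below random lists for megakaryocyte (2010 bp) and endothelial genes (1956 bp) without replicate 2, against 4571 bp and 2701 bp without replicate 1, and for endothelial genes with −log10 q of at least 5 (2193 bp) and with peaks in both own lists (2123 bp). Germ cell genes moved above without replicate 2 (2449 bp, against 2147 bp without replicate 1). Macrophage genes moved above in the pooled list (3233 bp), at 20 kb (1277 bp) and without promoter peaks (1185 bp). At 20 kb, granulocyte (672 bp) and gut and lung genes (251 bp) moved below and stellate genes (612 bp) above. T lymphoid (6893 bp) and muscle genes (6051 bp) moved above at 100 kb, and postnatal hepatocyte genes without promoter peaks (409 bp).

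In large domains, hepatic secreted proteins moved below other genes with either replicate left out (12.1%), with −log10 q of at least 5 and with peaks in both own lists (9.09% each), and at 5 kb stitching and without promoter peaks (3.03% each). Granulocyte genes moved below without replicate 2 (12.5%), at 5 kb stitching (6.25%) and without promoter peaks (0%). Endothelial genes moved above without replicate 1 and in the pooled list (15.4% each, against 11.5% without replicate 2). Stem and progenitor genes moved above at 5 kb stitching (8.33%) and without promoter peaks (4.17%). Without promoter peaks, hepatic transcription factors (4.55%), gut and lung (5.88%) and germ cell genes (5%) moved above. MEF2 fell to 1.00 with −log10 q of at least 5, 0.962 with peaks in both own lists and 0.826 within 100 bp, and RFX to 0.857 within 100 bp.

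Unknown depth keeps open whether peaks missing from a list lacked acetylation or lacked reads.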

Other observations

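The tests of the endothelial promoters against other genes and of base composition were chosen after their results, or values close to them, had been seen; the comparisons of promoter fold enrichment and of non-coding genes were also added after the data were examined.

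Among genes with a promoter peak, the erythroid, globin and iron handling lists had higher fold enrichment than random lists, and 9 lists had lower. Lists were not compared with each other. Each value is that of a whole peak, and some peaks at erythroid genes were very wide. Zfpm1 had 33.3 from a peak of 52.3 kb, Ank1 43.2 from 36.3 kb and Hemgn 40.7 from 19.9 kb. Peak width was not matched, so it cannot be told apart from enrichment at the promoter itself. The median promoter fold enrichment was 33.1 for the 40 marked erythroid genes, above all 10000 random lists of marked genes (median 11.4, permutation p = 0.0002, the smallest they can give, adjusted p = 0.00107 over 16 lists with at least 5 marked members). Globin genes had 29.9 (adjusted permutation p = 0.0101) and iron handling genes 22.6 (adjusted p = 0.0499). Medians were lower than in random lists for endothelial genes at 3.97 and stellate and mesothelial genes at 4.08 (both adjusted permutation p = 0.00107). They were also lower for postnatal hepatocyte genes at 4.43, hepatic secreted proteins at 4.80, macrophage genes at 5.03 and hepatic transcription factors at 5.04, with adjusted permutation p from 0.00160 to 0.0358, and for megakaryocyte (5.57), stem and progenitor (5.92) and hepatoblast and bile duct genes (5.03), with 0.0256, 0.0256 and 0.0499. Against random lists matched on promoter CpG content, the erythroid, globin, iron, endothelial, stellate and hepatic transcription factor lists still passed, and the hepatic secreted protein list did not (adjusted permutation p = 0.140); nor did the other lists that had been lower. Among genes whose peak held no TSS of another gene, the iron handling (21.7, adjusted permutation p = 0.0513), stem and progenitor (0.0645), megakaryocyte (0.0992) and hepatoblast and bile duct (0.0952) lists no longer passed, and the cell cycle list did (17.3, 0.0240). The globin list had too few such genes for this test.

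The following non-coding genes were chosen before their values were seen. The adjacent microRNA genes Mir144 and Mir451a, known from red-cell maturation, shared a peak of 61.3 within 1 kb of their 5′ ends (chromosome 11, from 78073005). Mir17hg had 22.7, H19 9.67 and Meg3 4.75. The hepatocyte microRNA gene Mir122 had no peak within 1 kb of its annotated 5′ end in the replicated list or in either replicate's own list. Neither had Mir124a-1hg, Mir133a-1hg or Mir9-3hg, which belong to nerve and muscle. The annotated Mir122 gene is short (chromosome 18, 65248861 to 65248926), so acetylation at a more distant promoter was not examined. On the X chromosome 30.6% of protein-coding genes had a promoter peak, and on the Y chromosome 2 of 183. Both pools held male and female embryos.

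The median promoter fold enrichment was 33.1 in the erythroid list and 4.80 in the hepatic secreted protein list, each compared only with random lists. Promoter CpG content was not the whole cause of the erythroid value, and stays open for the hepatic secreted protein list: the erythroid median stood at percentile 100 of CpG-matched random lists. Peaks shared with neighbouring promoters did not account for the erythroid value either, since among genes whose peak held no TSS of another gene the erythroid median, 32.3, was again at percentile 100. A candidate explanation is that erythroid cells made up most of the tissue, so that signal from other cells was diluted. Peak width was not matched in these comparisons and stays open. No biological explanation was tested, because the design has 1 group and cell proportions were not measured.

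Endothelial genes gained promoter peaks from the replicated to the pooled list, and some of these genes also had a peak in a replicate's own list. Of the 14 endothelial genes without a replicated promoter peak, 9 (64.3%) had 1 in the pooled list, against 9.82% of other such genes (Fisher's exact test, p = 1.11e-06, adjusted p = 2.76e-05 over the 25 lists), which argues against a general gain in the longer list. A weak signal from cell types that are a minority in the liver may contribute: unmarked macrophage, megakaryocyte, stem and progenitor, and stellate and mesothelial genes gained a pooled peak in 13 of 39 cases, and unmarked genes of the 6 other-tissue lists in 2 of 113 (Fisher's exact test, p = 2.66e-07). The 4 lists were tested together and not against each other; the gains were 6 of 15 macrophage, 3 of 6 megakaryocyte, 2 of 8 stem and progenitor, and 2 of 10 stellate and mesothelial genes. Gains were not limited to them. Hepatic transcription factors gained 2 of 4, hepatic secreted proteins 2 of 7, hepatoblast and bile duct genes 2 of 8 and granulocyte genes 4 of 13. B lymphoid genes gained 1 of 16 and T lymphoid genes 2 of 16. The other-tissue share, 1.77%, lay below the 9.82% given above, which widens the contrast. Differences in promoter composition between these lists were not matched and stay open, and no biological explanation was tested in a second group.

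The slight excess of WGATAR at distal peaks was set against the share of its reversed form. This excess passed in neither replicate's own list and not in the pooled list. Among windows holding either WGATAR or its reversed form but not both, the odds of WGATAR were 1.56 times higher in peak than in control windows (95% interval 1.46 to 1.67), and 1.24 times within 100 bp of the summit (1.15 to 1.34). Both forms hold the same bases, so these values argue against base composition as the whole cause of the difference in odds. They do not weigh it for the excess itself, because peak windows were richer in G and C, which would lower WGATAR. The odds came mainly from a rarer reversed form (46.5% against 53.3%), with WGATAR at 61.0% against 59.5%. Within 100 bp of summits WGATAR showed no excess (0.805), and the reversed form had a lower share as well (0.708 of the control share). Preferences for the order of neighbouring bases were not tested.

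Whether distal peaks of the large domains carry WGATAR more often, and HNF4 sequences less often, than other distal peaks was left undecided. Only distal peaks with a usable control window were counted, 3780 inside large domains and 17399 outside. Distal peaks with another peak 5 kb downstream were left out, so the shares do not describe all distal peaks of the domains. WGATAR was found in 59.6% of the counted peaks inside large domains and 61.3% outside (ratio 0.972, p = 0.0511, two-sided Fisher's exact test). In control windows the ratio was lower, 0.930, and the difference between these ratios was not tested. The HNF4 sequence was found in 0.979% inside and 1.14% outside (exact p = 0.441).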
